A study of Mus musculus with 6 samples.

How the data were processed

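Polyadenylated RNA of mouse late spermatocytes was sequenced from 6 libraries. GEO's labels place 3 libraries in the Mov10l1 fl/+ group and 3 in the Mov10l1 s fl/- group, and describe the libraries as directional. Per the labels' protocols, RNA was extracted with Trizol from testes or from sorted cells, and which of these applied to each library is not given in the sources used here. Per the submitters' processing notes, the reads were processed with TopHat and Bowtie on the mm9 build, without versions. The program that computed a value per gene, the gene annotation and any filter on genes are not given in the sources used here.

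The authors deposited 1 table, used here with 11421 rows and 8 columns and without a header line. Rows of the authors' table may have been left out of the copy used here, which would lower some of the shares given. The first column holds Ensembl gene identifiers and the second holds gene symbols, as deposited by the authors. The other 6 columns hold values whose unit is not named. No column name ties any of these 6 columns to a library or a genotype, and a library's genotype was not inferred from column order or from the values themselves. These 6 columns were therefore not used, no expression level, depth, fold change or test between the genotypes is given, and the comparison of Mov10l1 s fl/- with Mov10l1 fl/+ was not analysed here. The tests between genotypes, and the rule for naming changed genes, that were fixed before the data were examined could not be applied for the same reason.

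What was analysed is which genes the table lists. Gene content was chosen for analysis after the table was seen. Identifiers were matched without version numbers to the GENCODE M21 annotation of the GRCm38 build, which is not the build of the submitters' processing. Only names, gene types, chromosomes and transcript lengths were taken from it, and the coordinates given are those of GRCm38. The background was the set of 22028 protein-coding genes of that annotation. The share of genes listed was compared by chromosome, each against the other autosomes or, for X, Y and the mitochondrial genome, against all autosomes. It was also compared for 23 gene lists with 615 entries, each against all other protein-coding genes. The lists of pathways, meiotic and spermatid transcripts and markers of other testis cells were fixed before the data were examined. Of the list entries, 594 matched an annotated symbol, 11 matched through a RefSeq synonym and 10 were not matched.

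Two-sided Fisher's exact tests were used, with conditional odds ratios and their exact 95% intervals. P-values were adjusted by the Benjamini-Hochberg method over the 22 chromosomes or the 23 lists, with a threshold of 0.05. Shares carry exact Clopper-Pearson 95% intervals. These tests are across genes. Genes are not independent replicates, and the p-values say nothing about the spread between libraries. A gene called not listed has no row under its GENCODE M21 identifier in the table as used here. It can have a row under a retired identifier, since 175 identifiers of the table were not in the annotation. Of the list entries not listed by identifier, 1 (Spata22) had its symbol in the table, and 10 had an identifier newer than the 99th percentile of those listed. The absence of a gene was not read as a lack of expression or as the authors' choice. Nor does the presence of a row show that a gene was expressed, since the values were not used. The test was tested on simulated data over the 22028 genes. Among 100 random lists of 30 genes with no effect it called 5 at an unadjusted p under 0.05, and among 100 lists drawn with an odds ratio of 4 it called 91, with a median odds ratio of 3.97. For random lists a rate near that threshold is built into the test, so the simulation checks the calculation only. It does not cover lists of related genes or the adjusted p-values used here. Python 3.11.15, SciPy 1.17.1, statsmodels 0.14.6, pandas 2.3.3 and NumPy 2.4.6 were used. The alternatives tried were a background limited to identifiers no newer than the 99th percentile of those listed, a match by symbol, genes of all types, 5 strata of transcript length, and the removal of gene families, of clone names, and of both. A gene family was a symbol stem shared by at least 3 protein-coding genes of 1 chromosome, and clone names were those starting with Gm and a number or ending in Rik.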

Results

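Late spermatocytes are male germ cells in the later part of meiotic prophase. The series concerns such cells deficient in pachytene piRNAs, small RNAs of meiotic germ cells that are bound by PIWI proteins. It set out to compare polyadenylated RNA between 3 Mov10l1 fl/+ libraries and 3 Mov10l1 s fl/- libraries. Mov10l1 encodes an RNA helicase required for piRNA production. The values per library could not be assigned to a genotype, because the table's 6 columns of values carry no names. The genotype comparison is therefore not given, and neither are levels of Mov10l1 in the individual libraries. The depth of the libraries is unknown. The gene content of the table, which the 6 libraries share, is described here.

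The table listed 11421 genes, of which 11246 (98.5%) had an identifier in the GENCODE M21 annotation. Of the matched genes, 11067 (98.4%) were protein-coding. They made up 50.2% of the 22028 annotated protein-coding genes, a share that would be higher if the authors' table holds rows that were not analysed here. This background holds families hardly listed, such as olfactory receptors (3 of 1135), while 45 of 46 genes named Nduf were listed. A list above 50.2% is therefore not by that alone particular to these cells. The matched genes also held 37 lincRNAs, 28 antisense transcripts and 56 processed pseudogenes. Mov10l1 was listed, with the identifier ENSMUSG00000015365. It lies on the plus strand of chromosome 15 from 88982909 to 89055152 in GRCm38 and is annotated as protein-coding.

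The list named for the later stages of meiosis was listed in full. All 36 genes of the late spermatocyte and meiotic division list were present, against 50.2% of other protein-coding genes. The exact lower bound of the odds ratio was 9.21 (Fisher's exact test, adjusted p = 6.6e-10). They included Ccna1, a cyclin of male meiosis, Hspa2, a chaperone of spermatocytes, and the kinases Plk1 and Aurkc. This list also holds genes of cell division in general, such as Plk1, Cdk1, Ccnb1 and Bub1. Its share is therefore not that of meiotic genes alone. The synaptonemal complex and crossover list had 21 of 24 genes listed (87.5%; adjusted p = 0.000794, Fisher's exact test). Sycp1 and Sycp3, structural proteins of the synaptonemal complex, and Msh4 and Msh5, crossover proteins, were among these, while Tex11 and Brip1 were not. Spata22 counted as not listed by identifier, but its symbol was in the table under another identifier. The early meiotic prophase list had 18 of 27 genes listed (66.7%), which did not pass the test (adjusted p = 0.156, Fisher's exact test). The list passed only against genes of all types, of which the table lists few (adjusted p = 3.99e-07, exact test). Spo11, the enzyme that makes meiotic DNA breaks, was listed. Stra8, a gene of meiotic entry, and Dmc1, a meiotic recombinase, were not among the listed genes.

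The piRNA pathway list had 25 of 28 genes listed (89.3%, exact 95% interval 71.8 to 97.7; adjusted p = 0.000126, Fisher's exact test). Piwil1 and Piwil2, the PIWI proteins known as MIWI and MILI, were present, as were the Tudor-domain genes Tdrd1, Tdrd6 and Tdrd9. Mybl1, a transcription factor of pachytene piRNA genes, was also present. Piwil4, Tdrd5 and Btbd18 were not listed. The microRNA and siRNA machinery had 14 of 15 genes listed (93.3%; adjusted p = 0.00224, Fisher's exact test), including Dicer1, Drosha and Ago2. With genes matched by symbol in place of identifier the share fell to 60% and this call was lost (adjusted p = 0.329, Fisher's exact test). Symbols differed from the annotation for 1385 identifiers. A gene listed by identifier is missed by symbol only where the symbols differ, so the drop reflects gene names and not missing rows. DNA methylation and heterochromatin genes were listed at 15 of 21 (71.4%, adjusted p = 0.106, Fisher's exact test). They passed the threshold with a match by symbol (adjusted p = 0.0297, exact test) and against genes of all types, of which the table lists few (adjusted p = 9.26e-07, exact test). With a match by symbol their own share stayed at 71.4%, while the share of other genes fell. Of autosomal protein-coding genes, for example, 46.0% were listed by symbol and 51.8% by identifier. Dnmt1 and Dnmt3l were present and Dnmt3a, Tet1, Tet2 and Tet3 were not.

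The lists named for post-meiotic cells were listed nearly in full. Their rows do not show that these genes were expressed in late spermatocytes, since the values were not used. The round spermatid list had 41 of 43 genes present (95.3%; adjusted p = 2.15e-09, Fisher's exact test), among them Acrv1, an acrosomal protein, and Crem, a transcription factor of spermatids. Tssk6 and Lrrd1 were not listed. The elongating spermatid list had 33 of 35 genes present (94.3%; adjusted p = 2.09e-07, Fisher's exact test). It included the protamines Prm1 and Prm2, which package sperm DNA, and the transition proteins Tnp1 and Tnp2. Genes of germ cell energy metabolism were listed at 19 of 20 (adjusted p = 0.000131, Fisher's exact test), including Ldhc and Pgk2, the germ cell forms of lactate dehydrogenase and phosphoglycerate kinase.

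DNA damage signalling and repair genes were listed at 37 of 38 (97.4%, adjusted p = 2.15e-09, Fisher's exact test). A share this high was also found for the housekeeping genes named Nduf (45 of 46). Atm, Atr, Brca1 and H2afx were present and Chek2 was not. The p53 response list had 19 of 30 genes listed (adjusted p = 0.243) and the apoptosis list 18 of 31 (adjusted p = 0.544), neither past the threshold of Fisher's exact test. Both passed it against genes of all types (adjusted p = 5.68e-07 and 6.13e-06, exact test). So did most lists, 20 of 23 being more often listed there, because the table lists few genes of other types. Passing against that background therefore says little about a list. Unfolded protein and heat shock genes were listed at 24 of 29 (adjusted p = 0.00139) and immediate early genes, such as Fos and Jun, at 18 of 21 (adjusted p = 0.00311, Fisher's exact test for both). The interferon response list had 10 of 30 genes listed (33.3%; adjusted p = 0.0996, Fisher's exact test). The direction depended on the background. The list was less often listed than other genes with older identifiers (adjusted p = 0.0272) and, matched by symbol, not past the threshold (adjusted p = 0.311, Fisher's exact test for both). It was more often listed than genes of all types, of which the table lists few (adjusted p = 0.04999, exact test).

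Markers of other testis cells differed in how often they were listed. Spermatogonia markers were listed less often than other genes, at 6 of 27 (22.2%, exact 95% interval 8.62 to 42.3; adjusted p = 0.00628, Fisher's exact test). Gfra1, Kit, Id4, Uchl1, Etv5 and Itga6 were present, and Zbtb16, Sohlh1 and Nanos2 were not. The low share was relative to protein-coding genes and was lost against genes of all types (adjusted p = 0.847, exact test), of which the table lists few. None of 9 blood cell transcripts was listed (exact upper bound 33.6%; adjusted p = 0.00358, Fisher's exact test), a call also lost against genes of all types (adjusted p = 0.24). Leydig cell markers were listed at 19 of 20 (95%; adjusted p = 0.000131, Fisher's exact test), including the steroidogenic genes Star, Cyp11a1, Cyp17a1 and Insl3, a Leydig cell hormone. By the same exact test, Sertoli cell markers were listed at 16 of 28 (adjusted p = 0.626), peritubular, stromal and endothelial markers at 11 of 23 (adjusted p = 0.851), and macrophage and leukocyte markers at 16 of 22 (adjusted p = 0.0804). None of these 3 lists passed the threshold against other protein-coding genes. Against genes of all types, of which the table lists few, each was more often listed (adjusted p = 2.62e-05, 0.00335 and 3.2e-07, exact test). Of the Sertoli cell markers, Clu and Vim were present, whereas Sox9 and Wt1 were not. Col1a1 and Dcn were present among the peritubular, stromal and endothelial markers, and Acta2 and Pecam1 were not. Among macrophage and leukocyte markers Cd68 was present and Ptprc was not.

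**Figure D1:**
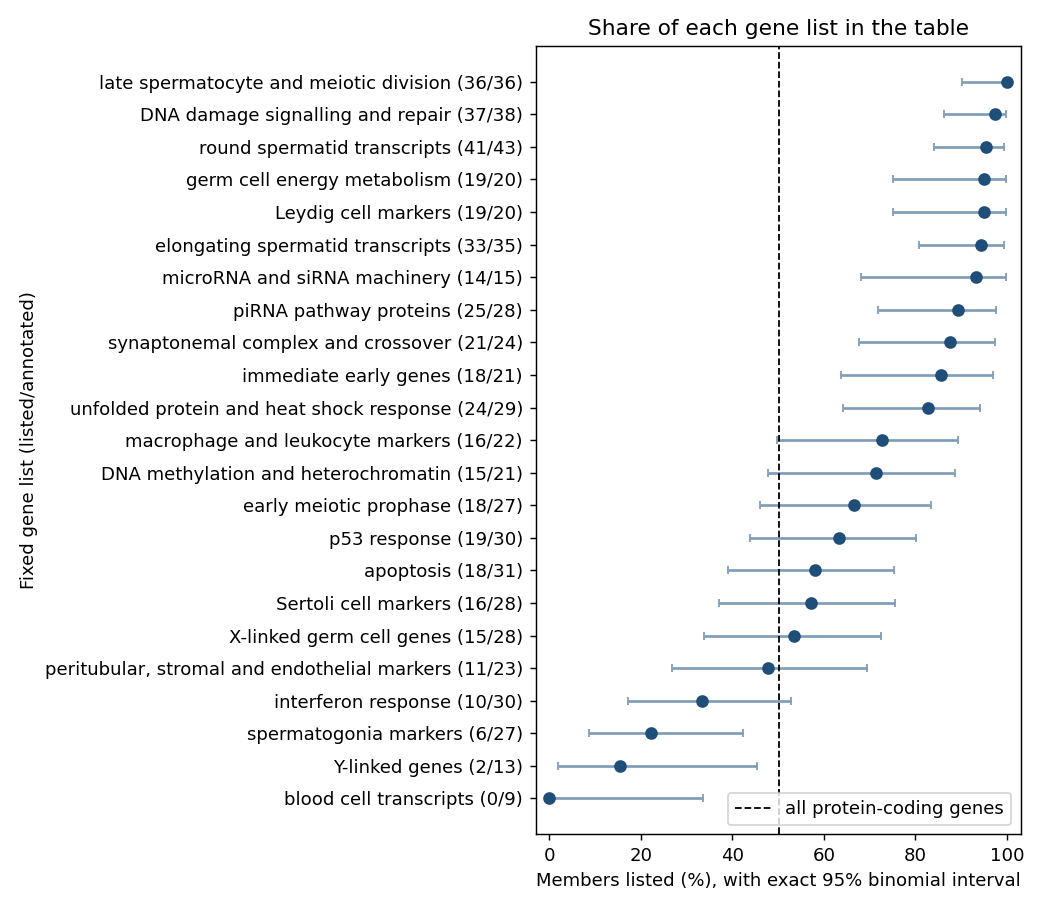
Share of each fixed gene list present in the table (x axis, percent of annotated protein-coding members, with exact 95% binomial intervals), 1 row per list with the numbers listed and annotated. The late spermatocyte list sits at 36 of 36 and blood cell transcripts at 0 of 9, on either side of the 50.2% of all protein-coding genes (dashed line).

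Genes of the sex chromosomes were listed less often than autosomal genes. Of 948 X-linked protein-coding genes 279 were listed (29.4%, exact 95% interval 26.5 to 32.4), against 51.8% of autosomal genes. The odds ratio was 0.388 (95% interval 0.335 to 0.448; adjusted p = 2.05e-41, Fisher's exact test). Of 183 Y-linked protein-coding genes 2 were listed, Ddx3y and Eif2s3y (odds ratio 0.0103, adjusted p = 8.74e-53, Fisher's exact test). The background of older identifiers was not applied to the Y chromosome as a whole. How far Y-linked genes missing from an older build or annotation account for this value was therefore not tested. None of the 13 protein-coding genes of the mitochondrial genome was listed (adjusted p = 0.000185, Fisher's exact test). The fixed list of X-linked germ cell genes had 15 of 28 protein-coding members present (53.6%; adjusted p = 0.851, Fisher's exact test). That test was against all other protein-coding genes. The list was not tested against X-linked genes alone, of which 29.4% were listed. Against genes of all types, of which the table lists few, the list was more often listed (adjusted p = 0.000209, exact test). Among the members present were Akap4, a sheath protein of the sperm tail, and Taf7l, while Pgk1 and Tex11 were not listed. The list also holds genes not particular to germ cells, such as Hprt, Uba1 and Pdha1, which were listed, and Pgk1. Its share is therefore not that of germ cell genes alone. The fixed Y-linked list had 2 of 13 present (adjusted p = 0.0206, Fisher's exact test), a call that was lost with a background of older identifiers (adjusted p = 0.134), with a match by symbol (adjusted p = 0.0729) and against genes of all types (adjusted p = 1). Among autosomes, chromosome 8 had the highest share listed (60.1%, exact 95% interval 57.0 to 63.1) and chromosome 7 the lowest (42.5%, 40.3 to 44.6). Both passed Fisher's exact test against the other autosomes (odds ratios 1.42 and 0.659, adjusted p = 2.26e-07 and 5.22e-18). Chromosomes 4, 5, 11 and 12 were also more often listed, and 6, 13 and 14 less often. Passing this test is therefore not particular to the sex chromosomes.

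**Figure D2:**
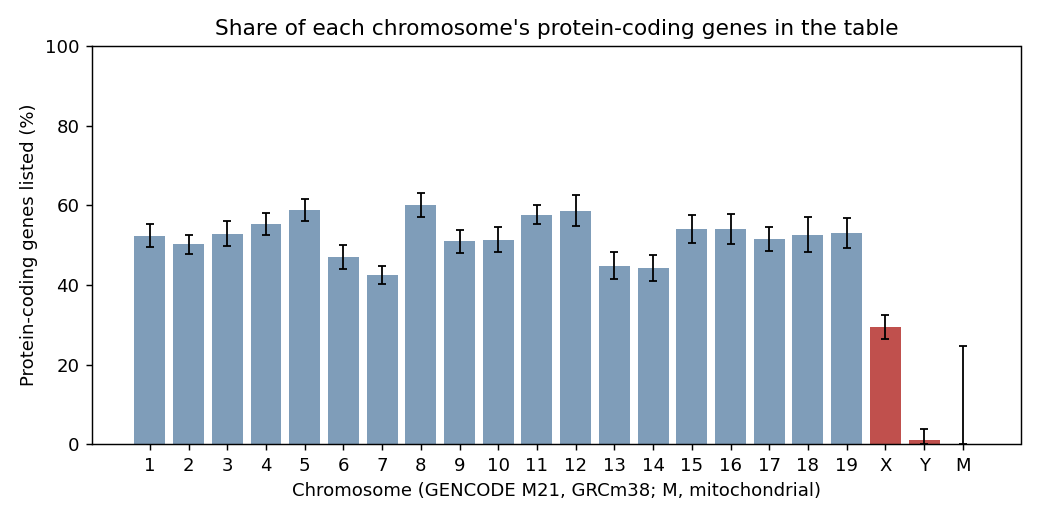
Share of annotated protein-coding genes present in the table (y axis, percent, with exact 95% binomial intervals) for each mouse chromosome (x axis; sex chromosomes and the mitochondrial genome in red). Autosomes range from 42.5% to 60.1%, above the 29.4% of the X chromosome.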

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

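All alternatives here were chosen after the table was seen. No paired analysis was possible because the value columns carry no sample names, and the alternatives of normalization, filter, pseudocount, variance model and left-out libraries that were set before the data were examined were not run for the same reason. X-linked genes were listed less often than autosomal genes under each of the 7 alternatives, with odds ratios from 0.334 (without gene families and clone names) to 0.442 (genes of all types). Of the 23 fixed lists, 11 were more often and 3 less often listed than other genes, and a match by symbol gave 11 and 2. With genes of all types as the background 20 lists were more often listed and 0 less often, because that background adds gene types that the table hardly lists (98.4% of matched genes were protein-coding). Over the lists and the 3 alternatives to the background or matching, 52 single-list results stayed on their side of the threshold, 11 moved past it and 6 fell short of it, and 4 of all these changed direction. Against genes of all types, interferon response (35.5% listed), spermatogonia markers (22.2%) and peritubular, stromal and endothelial markers (47.8%) turned from below to above the other genes. With a match by symbol the last of these, again at 47.8%, did so too. The depth behind the values is unknown, so no limit of detection can be given.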

Other observations

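The tests on X-linked genes by identifier age, by transcript length, and without both gene families and clone names were set down before their results were seen. No such record exists for those without clone names alone, with a match by symbol or with genes of all types. The test without gene families alone, the tests on autosomes 6, 7, 13 and 14 and the counts of gene families were chosen afterwards. Large families expressed in sensory neurons had few rows in the table, with 3 of 1135 olfactory receptor genes and 1 of 210 vomeronasal 1 receptor genes listed, and 0 of 121 vomeronasal 2 receptor genes. Housekeeping families, picked by the start of the symbol alone, were mostly present. Of the genes named Nduf, 45 of 46 were listed, as were 23 of 26 named Psma, Psmb or Psmc. Of the genes named Rpl, 43 of 54 were listed, and of those named Rps 38 of 45. The proteasome genes named Psmd were not counted, and the Rps count also took in kinase genes such as Rps6ka3.

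Leydig cell markers stood out after the counts were seen, with 19 of 20 listed, beside 16 of 22 macrophage and leukocyte markers, 16 of 28 Sertoli cell markers, 11 of 23 peritubular, stromal and endothelial markers and 6 of 27 spermatogonia markers. With a match by symbol the Leydig share was 85% in place of 95%, because some symbols differ from the annotation, and the Sertoli share stayed at 57.1%. A test between lists singled out for their shares would restate that choice, so none is given. Whether the listed Leydig genes stand at low or high levels, and in which libraries, was not analysed here.

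X-linked genes were listed at 29.4% and autosomal genes at 51.8%. A newer annotation than the authors' as the whole cause is argued against by the odds ratio of 0.388 (95% interval 0.333 to 0.450) among genes with identifiers no newer than the listed ones. Gene length as the whole cause is argued against by an odds ratio of 0.427 (0.369 to 0.493) pooled over 5 strata of transcript length. Gene families, picked by symbol stem and not by position, are argued against as the whole cause. The odds ratio was 0.342 (0.288 to 0.405) without them, clone names being kept, and 0.334 (0.276 to 0.404) without them and clone names. No biological explanation was tested. An unknown filter of the authors, and rows left out of the table as used here, also stay open.

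Autosomes 6, 7, 13 and 14, singled out for their low shares, together had 44.2% of their protein-coding genes listed, against 54.2% on the other autosomes (odds ratio 0.671, 95% interval 0.629 to 0.716). Without the gene families picked by symbol stem the odds ratio was 0.819 (0.755 to 0.888), without clone names 0.686 (0.641 to 0.735), and without both 0.913 (0.835 to 0.998). An odds ratio below 1 follows in part from choosing these chromosomes for their low share, so how much of the difference clustered gene families account for stays open.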
